A study of Mus musculus with 6 samples.

How the data were processed

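Total RNA from 6 mouse neural stem cell lines was hybridised to 6 Affymetrix arrays, 1 array per line. The labels put 3 lines in a FoxO-null group and 3 in a wild-type group, and they call the lines independent. Biotinylated cRNA was made from 6 ug of total RNA, per the labels' protocols. The deposited values are intensity signals that the authors made with MAS5, per the submitters' processing notes, which give no version of it. The labels name no further step. On each of the 6 arrays the mean signal after trimming 2% of the values at each end was 100, so the values were treated as linear signals that the authors had already scaled to a common target. Array medians lay between 25.5 and 32.8. Their highest over lowest ratio of 1.29 was under the limit of 1.5 at which the arrays would have been quantile normalized, so the deposited scaling was kept. No detection calls were used here. Every value column of the table was used, and 0 were left out.

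The table held 45101 probe sets, of which 64 were controls. A table pairing probe sets with the platform's annotation gave 1 gene to 34945 of the others, several genes to 932 and no gene to 9160. Symbols were checked through gene numbers: 34754 of 35890 annotated probe sets matched the mouse gene table and 0 symbols differed. Probe sets with several genes or none were named after no gene. The 34945 probe sets with 1 gene stood for 18193 genes. Each gene was represented by the probe set with the highest mean log2 value over the 6 arrays, and probe sets that disagree within a gene are given as such for the FoxO genes.

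Signals were turned into log2(signal + 5.94), the offset being the 20th percentile of all values. Fold changes are on that scale, which understates the change of weakly expressed genes. Genes whose mean log2 value lay under the 40th percentile of all non-control probe sets, equal to a signal of 16.2, were left out, and 12665 genes were tested. The comparison was fitted with lmFit and eBayes (with an intensity trend) of limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). It had no covariates, and the test was two-sided. The threshold was a Benjamini-Hochberg adjusted p under 0.05. All p-values of single genes below come from this limma fit and treat the lines as independent, as the labels call them. The number of arrays limits the precision: an exact permutation test of a single value in 3 lines against 3 cannot give a two-sided p under 0.1. Values of single genes are mean MAS5 signals ± SD over 3 lines per group, and log2 fold changes are given ± the standard error of the fit.

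The FoxO probe sets were read from a fit of all 45037 non-control probe sets without the filter on low signals. The highest of the 27 Bacillus subtilis control probe sets on each array, between 14.4 and 27.6, served as that array's background level. It was 19.2, 27.6 and 26.9 on FoxO-null arrays 1 to 3 and 14.4, 15.8 and 19.1 on wild-type arrays 1 to 3. Background and group label thus went together. Where all 3 arrays of a group lay at or under it, a fold change was also given as a lower bound, from the geometric mean of the brighter group and that of the background levels of the other group's arrays.

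Gene lists for 34 pathways, cell types and FoxO target classes were fixed before the data were examined, as were the design and the alternatives, except where a choice is said to be later. The 33 lists with 4 or more measured members were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry, whose p tests whether a list's genes move one way on balance, were run beside it. The mixed test of fry, which looks for changes in either direction, was also run and is named as mixed. Members of a list were also counted after adjustment over that list alone. No cell type was assigned from the marker lists.

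Genes named in the text followed a rule fixed in advance. It took the FoxO genes, then the 10 largest rises and falls among genes past the threshold with groups that do not overlap. Where under 5 genes passed in a direction, it took the 10 genes of smallest p in that direction instead, leaving out clone and predicted gene names. Under 5 passed in both directions, so the latter applied to both. From each list it took up to 4 members past the threshold or, where none passed, up to 2 of smallest p. Aspm, Axin2, Sfrp1, Sfrp2, Lef1, Ccnd1, Ccng2, Cdkn1a, Cdkn1b, Cdkn1c, Sod2, Cat, Gfap, Nes, Sox2, Olig2 and Dcx were named whatever their values. Where a list below has other members named, they were chosen after their values were seen because they passed when adjusted over the list alone.

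The procedure was tested on simulated data for the comparison of FoxO-null with wild-type lines, with 12665 genes, 200 of them changed, in 10 simulations. It recovered 80.9% of genes changed 4-fold and 45.8% of genes changed 2-fold, and 4.67% of the calls were false. A list of 30 genes shifted by 0.35 was found, at an unadjusted camera p under 0.05, in 10 of 10 simulations with the preset and with the estimated correlation. Of lists without a shift, 2% were called by the same criterion with the preset and 0.5% with the estimated correlation. Lists in the data had to pass after adjustment over all lists tested, so these shares do not describe that stricter threshold. With the estimated correlation, 7 lists in the data had an unadjusted p under 0.05 and 0 passed after adjustment. The simulated genes varied independently of each other, so the list results do not cover lists whose genes vary together. In the data, the estimated correlation was 0.19 for the G2/M list, 0.59 for the hypoxia list and -0.051 for the microcephaly list.

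Alternatives covered quantile normalization, median centring, the offset, the filter, the choice of probe set, the variance prior, array weights, the threshold, the replicate number as a block, the list test and leaving out each array in turn. The state of Xist on each array, above or under a signal of 1000, was added as a block after the sex-linked signals had been seen.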

Results

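Transcript levels were measured in 6 mouse neural stem cell lines on 1 array per line. Neural stem cells are dividing cells of the brain that can give rise to neurons, astrocytes and oligodendrocytes. The labels describe 3 lines as lacking FoxO genes and 3 as wild type, and the comparison asks which transcripts depend on FoxO, a family of transcription factors that insulin and growth factor signalling holds out of the nucleus. Over 12665 genes tested, arrays of the same group correlated at a mean r of 0.957 and arrays of different groups at a mean r of 0.954, across genes, which are not independent replicates. The first principal component took 28.3% of the variance and did not part the groups. The FoxO-null 3 array had the lowest best correlation with any other array, 0.953. The 18S rRNA 5' control probe set read 211 on wild-type 1 and between 23.5 and 38.9 on the other arrays. Signals of Xist, the X-inactivation transcript, and of Y-linked genes showed that both groups mix lines with high Xist and lines with Y-linked transcripts: Xist was at 5922 on FoxO-null 2, 3733 on wild-type 1 and 6327 on wild-type 2, and between 25.5 and 35.8 on the other arrays.

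FoxO transcripts were not lower in the lines labelled FoxO-null; most of their probe sets were higher there. The labels do not say which FoxO genes were deleted, and Foxo1, Foxo3 and Foxo4 are taken here as the targeted genes. Of 9 probe sets for these genes, 8 had a positive log2 fold change (FoxO-null minus wild-type), and 5 had all 3 arrays labelled FoxO-null above all 3 arrays labelled wild-type. The Foxo1 probe set of highest mean signal read 77.9, 77.8 and 100.3 on FoxO-null arrays 1 to 3 and 20.3, 20.4 and 31.7 on wild-type arrays 1 to 3, a log2 difference of 1.61 ± 0.29 with a limma adjusted p of 0.168 over the 45037 probe sets. The Foxo3 probe set of smallest p read 384, 423 and 454 against 207, 249.6 and 224, a log2 difference of 0.87 ± 0.13 (limma adjusted p 0.0882). The groups overlapped in the other 2 Foxo3 probe sets: the one of highest mean signal read 578, 667 and 856 against 267, 611 and 507 (0.66 ± 0.25, limma adjusted p 0.593), and the third differed by 0.95 ± 0.44 (0.692). The Foxo4 probe set of highest mean signal read 178, 57.2 and 189.9 against 5.56, 4.14 and 17.1, a log2 difference of 3.24 ± 0.48 (limma adjusted p 0.0882). Its wild-type signals all lay within the range of the bacterial control probe sets of their arrays, so its signal was at least 7.62-fold higher in the lines labelled FoxO-null. The other Foxo4 probe set disagreed, with means of 24.7 ± 11.8 and 31.0 ± 8.33 and a log2 difference of -0.31 ± 0.41. Its groups overlapped at signals near the bacterial controls. No probe set was named for Foxo6. Where these probe sets lie relative to the deleted exons is not known here, and a probe set outside the deleted part checks nothing. Because the signals go against the labels, the groups are called lines labelled FoxO-null and lines labelled wild-type throughout, and each direction below follows those labels.

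**Figure D1:**
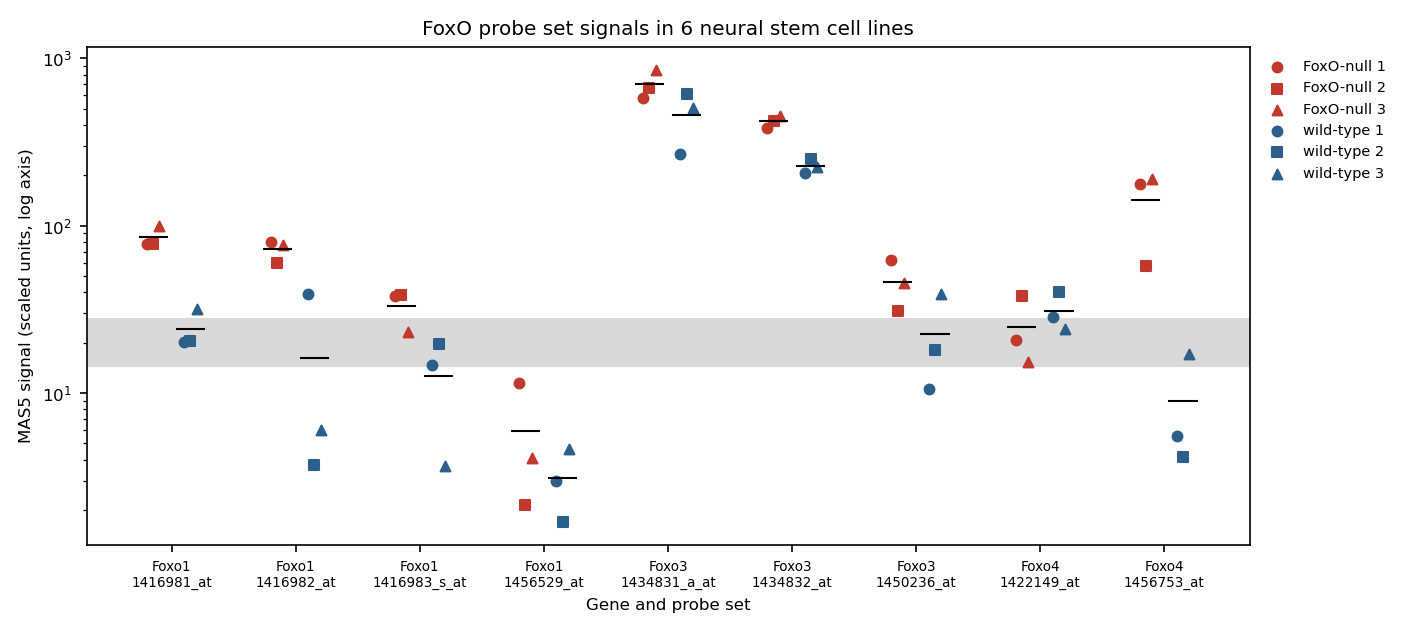
MAS5 signal (log axis) of the 9 FoxO probe sets on each of the 6 arrays; points are arrays, black lines are group means, and the grey band spans the highest bacterial control signal of the arrays, 14.4 to 27.6. In 5 of the 9 probe sets all arrays labelled FoxO-null lie above all arrays labelled wild-type.

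The lines labelled FoxO-null had higher glial transcripts and lower cell division transcripts than the lines labelled wild-type. Hes5, a Notch effector that keeps progenitors undifferentiated, rose by a log2 fold change of 1.41 ± 0.15, from a mean signal of 127 ± 11.1 to 350 ± 55.4 (n = 3 lines per group, limma adjusted p 0.0157). The calcium-binding protein gene S100a1 rose by 0.999 ± 0.13, from 284 ± 31.3 to 573 ± 64.1, and the myelin enzyme gene Cnp rose by 0.87 ± 0.12, from 1364 ± 116 to 2501 ± 327 (limma adjusted p 0.0471 each). Ccbe1, a secreted protein gene of lymphatic development, fell by 1.75 ± 0.25 on the log2 scale, from 310 ± 105 to 86.0 ± 19.5 (limma adjusted p 0.0471). As groups, G2/M, G1/S and microcephaly genes and p53 targets were lower, and astrocyte and oligodendrocyte lineage markers were higher, each with a camera adjusted p of 4.54e-05 or less. None of these 6 lists passed with an estimated correlation, where the smallest adjusted p = 0.103 with an estimated correlation.

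In all, 5 of 12665 genes passed the limma threshold, 4 higher and 1 lower in the lines labelled FoxO-null, and 3 of them changed at least 2-fold. Foxo4 was the remaining one, with a log2 fold change of 3.24 ± 0.46 (limma adjusted p 0.0471). Each of these 5 genes had all 3 arrays of one group above all 3 of the other. At an unadjusted limma p under 0.05 there were 1292 genes, 666 higher and 626 lower, against 633 given by chance and 320 to 1017 in the other 9 splits of the arrays into 3 and 3. The groups did not overlap in 2031 genes, which is 16.0% against the 10% that chance gives for 3 lines against 3. The median log2 fold change of all genes was 0.0098. The count of 5 was 0 without FoxO-null 1 (819 at an unadjusted limma p under 0.05), 1 without FoxO-null 3, 3 without wild-type 1 or wild-type 2, 13 without wild-type 3, of which 10 changed at least 2-fold, and 4 without FoxO-null 2. With median centring of the arrays 0 genes passed in limma (1048 unadjusted), and with quantile normalization 1 did. Hes5 lost its call without FoxO-null 1 (adjusted p 0.189), and S100a1, Cnp, Foxo4 and Ccbe1 passed in 2, 1, 2 and 1 of the 6 limma fits that left out 1 array, with adjusted p of up to 0.319, 0.319, 0.384 and 0.319 in the others.

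Fewer than 5 genes passed in each direction, so the 10 of smallest p per direction are described, most of which did not pass. On the higher side these included Glul, the glutamine synthetase gene of astrocytes, at 0.89 ± 0.13 (adjusted p 0.0504), and Gpr17, a receptor gene of oligodendrocyte precursors, at 0.73 ± 0.11 (0.0726). Foxo1 at 1.61 ± 0.26, the sodium pump subunit gene Atp1b2 at 0.90 ± 0.15, the glycogen-targeting phosphatase subunit gene Ppp1r3c at 0.84 ± 0.14 and the acetyl-CoA synthetase gene Acss1 at 0.84 ± 0.14 shared an adjusted p of 0.0729. On the lower side, the secreted olfactomedin gene Olfm2 had a log2 fold change of -0.76 ± 0.11 (0.0504) and the IGF-binding protein gene Igfbp4 one of -0.81 ± 0.14 (0.0894). The thymidine kinase gene Tk1 was at -0.66 ± 0.13 and the noradrenaline methyltransferase gene Pnmt at -1.86 ± 0.36 (0.131 each). Ddias at -0.56 ± 0.11, the polo-like kinase gene Plk2 at -0.90 ± 0.18, Rgl1 at -0.85 ± 0.17, Gt(ROSA)26Sor at -1.46 ± 0.30 and Msto1 at -0.66 ± 0.14 had an adjusted p of 0.136. Without wild-type 3, Foxo1 (1.78, adjusted p 0.0491), Atp1b2 (1.09, 0.0177), Ndrg2 (1.08, 0.0451) and Aspm (-0.96, 0.0314) passed over all genes, and so did Igfbp4 without FoxO-null 2 (-0.98, 0.0448).

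**Figure D2:**
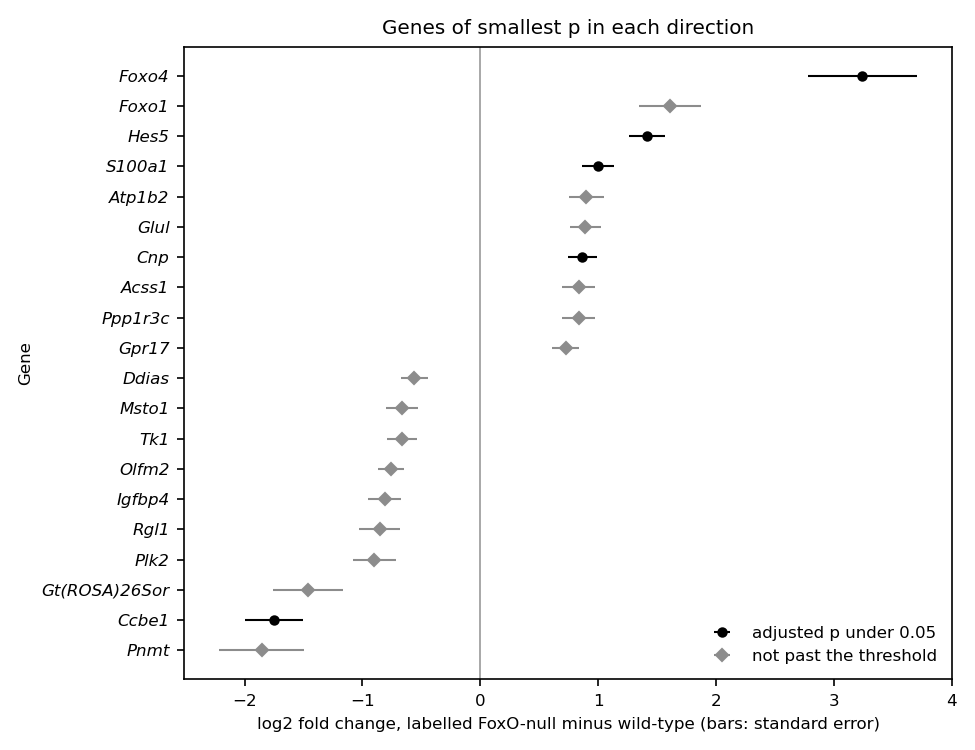
Log2 fold change (FoxO-null minus wild-type by label; bars, standard error of the limma fit) of the 10 genes of smallest p in each direction, 3 lines per group. Black circles mark the 5 genes past the adjusted threshold, of which Foxo4 at 3.24 is highest and Ccbe1 at -1.75 is the one that fell.

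Cell division transcripts moved together. Of 33 lists tested with limma's camera, 14 passed, 10 higher and 4 lower in the lines labelled FoxO-null. Several lists share genes, so the 14 calls are not separate findings. Aspm and Kif11 are in the G2/M and microcephaly lists, Hes5 in the stem cell and Notch lists, and Ldha in the hypoxia and glycolysis lists. With an estimated correlation 0 passed (7 had an unadjusted p under 0.05), and with fry 3 passed (9 unadjusted): the microcephaly, oligodendrocyte and G2/M lists. The G2/M and mitosis list had a median log2 fold change of -0.34, a ratio of 0.789, with 40 of 41 measured members negative (camera adjusted p 9.25e-20). For it, adjusted p = 0.156 with an estimated correlation. None of its members passed over all genes in limma (26 unadjusted), and 11 passed as lower when adjusted over the list alone. They included Aspm, which organises the spindle poles and is a microcephaly gene, at -0.76 ± 0.16 (586 ± 50.9 against 1011 ± 234, adjusted p 0.160 over all genes), and the mitotic kinesin gene Kif11 at -0.51 ± 0.12 (217 ± 8.64 against 313 ± 12.3). The G1/S and DNA replication list had a median of -0.35 with 36 of 38 members negative (camera adjusted p 2.6e-18). Here adjusted p = 0.166 with an estimated correlation. No member passed over all genes in limma (22 unadjusted) and 16 passed as lower when adjusted over the list alone, among them Tk1, the replicative helicase gene Mcm5 at -0.55 ± 0.12 and the cyclin D1 gene Ccnd1 at -0.63 ± 0.14 (2899 ± 571 against 4443 ± 373, adjusted p 0.187 over all genes). Without FoxO-null 1 the 2 counts adjusted over the list alone were 0 and 0, without wild-type 1 they were 3 and 7, and without wild-type 3 they were 2 and 9, while both lists kept their camera calls in each fit that left out 1 array.

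The microcephaly and centrosome genes were lower in all 17 measured members, with a median of -0.25 (camera adjusted p 6.69e-06). For this list adjusted p = 0.103 with an estimated correlation, and the fry adjusted p was 0.00133. Over all genes 0 passed in limma (4 unadjusted), and 3 passed as lower when adjusted over the list alone: Aspm, Kif11 and the kinetochore gene Knl1 at -0.65 ± 0.16. The p53 target list had a median of -0.31 with 19 of 22 members negative (camera adjusted p 4.54e-05). For it adjusted p = 0.156 with an estimated correlation. Over all genes 0 passed in limma (6 unadjusted) and 2 passed as lower when adjusted over the list alone, Plk2 and Gtse1, a G2 and S phase gene, at -0.64 ± 0.18; without FoxO-null 1 the count was 0, and without FoxO-null 3 or wild-type 2 it was 1. Without wild-type 1, the array with the high 18S rRNA control, the median of the p53 list was -0.15.

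Markers of both glial lineages were higher in the lines labelled FoxO-null. The astrocyte list had a median log2 fold change of 0.39, with 14 of 17 measured members positive (camera adjusted p 6.03e-09). For it adjusted p = 0.180 with an estimated correlation. Over all genes 0 members passed in limma (9 unadjusted), and 7 passed as higher when adjusted over the list alone, among them Glul (699 ± 113 against 371 ± 9.62) and Ndrg2 at 0.93 ± 0.16 (677 ± 123 against 352 ± 67.0); the count was 4 without FoxO-null 1. Gfap, the astrocyte filament gene, was at 0.36 ± 0.19 (adjusted p 0.562). The oligodendrocyte lineage list had a median of 0.48 with 19 of 22 members positive (camera adjusted p 6.38e-09). Here adjusted p = 0.103 with an estimated correlation, and the fry adjusted p was 0.0445. Cnp passed over all genes, and 10 members passed as higher when adjusted over the list alone, including Gpr17 (703 ± 59.2 against 422 ± 22.4); the count was 5 without FoxO-null 1. Olig2, a lineage transcription factor gene, was at -0.18 ± 0.11 (adjusted p 0.617).

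**Figure D3:**
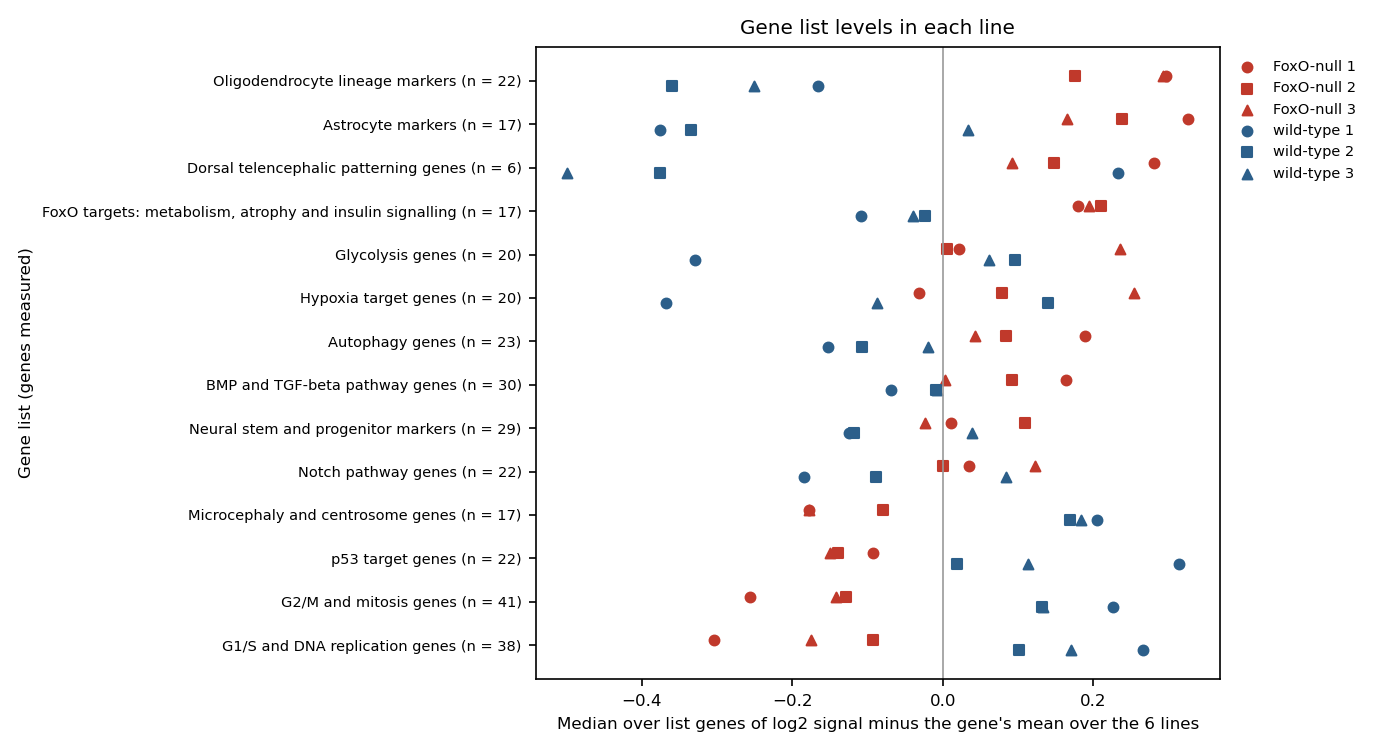
Level of the 14 lists past the camera threshold on each array: the median over list genes of log2 signal minus the mean of the gene over the 6 lines (n, genes measured). In the G2/M, G1/S, microcephaly and p53 lists all 3 lines labelled FoxO-null lie below all 3 labelled wild-type, and in the astrocyte and oligodendrocyte lists all 3 lie above. All 3 also lie above in the autophagy, BMP and TGF-beta and FoxO metabolism lists. The 14 lists were picked for a group difference on these same arrays.

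Stem cell and signalling lists shifted less. The neural stem and progenitor list had a median of 0.10 with 17 of 29 members positive (camera adjusted p 0.0209). There adjusted p = 0.256 with an estimated correlation. Hes5 passed over all genes and 6 members passed when adjusted over the list alone, 5 higher (Hes5, Id1, Nr2e1, Slc1a3 and Hey1) and 1 lower (Tnc); this count was 2 without FoxO-null 1 and 3 without FoxO-null 3. The median of the list was -0.0083 without FoxO-null 2, 0.062 without wild-type 2 and 0.18 without FoxO-null 3 or wild-type 3, and its camera call was lost without FoxO-null 2 (0.117), wild-type 1 (0.0509) or wild-type 2 (0.0653). The progenitor filament gene Nes was at -0.36 ± 0.17 (adjusted p 0.491) and Sox2 at 0.10 ± 0.13 (0.839). The Notch list had a median of 0.085 with 15 of 22 positive (camera adjusted p 0.0365). For Notch adjusted p = 0.473 with an estimated correlation. Again Hes5 passed over all genes, and 5 passed when adjusted over the list alone: Hes5, Nrarp, Dll3 and Hey1 higher and the ligand gene Jag1 lower at -0.63 ± 0.17. That count was 1 without FoxO-null 1 or wild-type 2, 2 without FoxO-null 3 and 3 without wild-type 1, and the camera call was lost without FoxO-null 3 (0.0835) or wild-type 1 (0.288).

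The BMP and TGF-beta list had a median of 0.11 with 20 of 30 positive (camera adjusted p 0.0209). For it adjusted p = 0.180 with an estimated correlation. None passed over all genes and 3 passed when adjusted over the list alone: Id1 at 0.92 ± 0.17 (1026 ± 161 against 544 ± 127) and Id2 at 0.64 ± 0.12, inhibitors of differentiation that BMP signals induce, were higher, and the receptor gene Tgfbr2 was lower at -0.77 ± 0.19. Its median was 0.20 without FoxO-null 3, and its camera call was lost without FoxO-null 2 (0.0600). The 6 measured dorsal telencephalic patterning genes were all positive, with a median of 0.34 (camera adjusted p 0.0261). There adjusted p = 0.478 with an estimated correlation. Of these, none passed over all genes and Lhx2 passed as higher when adjusted over the list alone (1 gene, 0.68 ± 0.21), with Emx2 at 0.44 ± 0.25. Its camera call was lost without FoxO-null 1 (0.0846), FoxO-null 2 (0.0591), wild-type 2 (0.109) or wild-type 3 (0.216), and the count of genes adjusted over the list alone was 0 without any of these or FoxO-null 3 and was 3 without wild-type 1. The dorsal median was 0.22 without wild-type 2, 0.19 without wild-type 3 and 0.70 without wild-type 1. Relative to the mean of the 6 lines, the dorsal list stood at -0.38 on wild-type 2 and -0.50 on wild-type 3, where the posterior neural and Hox list stood at 0.32 and 0.69. On wild-type 1 the order was the opposite, 0.23 for the dorsal and -0.71 for the posterior list.

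Metabolic lists were higher. The FoxO targets of metabolism, atrophy and insulin signalling, which FoxO factors are known to switch on, had a median of 0.32, with all 3 lines labelled FoxO-null above all 3 labelled wild-type and 11 of 17 positive (camera adjusted p 0.0145). For them adjusted p = 0.253 with an estimated correlation. None passed over all genes, and 3 passed as higher when adjusted over the list alone: Pik3ip1, an inhibitor of PI3-kinase, at 0.94 ± 0.17 (293 ± 31.1 against 151 ± 30.6), Pdk4, a pyruvate dehydrogenase kinase gene, at 1.39 ± 0.29 (75.2 ± 25.1 against 24.2 ± 3.45), and Ddit4, which was at 0.33 without wild-type 1. Their median was 0.079 without wild-type 1, and the camera call was lost without FoxO-null 3 (0.0673). The hypoxia list had a median of 0.15 with 18 of 20 positive (camera adjusted p 0.00211). For hypoxia adjusted p = 0.739 with an estimated correlation. No member passed over all genes, and 0 passed when adjusted over the list alone (5 had an unadjusted limma p under 0.05), or 5 without wild-type 2; Ddit4 was at 0.56 ± 0.17 and Higd1a at 0.36 ± 0.14. The glycolysis list had a median of 0.16 with 17 of 20 positive (camera adjusted p 0.00244). For glycolysis adjusted p = 0.535 with an estimated correlation. None passed over all genes and 1, the phosphofructokinase gene Pfkp at 0.64 ± 0.14, passed as higher when adjusted over the list alone, but not without FoxO-null 1, and 2 passed without wild-type 2 or wild-type 3; Aldoc was at 0.59 ± 0.18, or 0.36 without wild-type 1. Relative to the mean of the 6 lines, wild-type 1, the array with the high 18S rRNA control, stood at -0.37 for hypoxia and -0.33 for glycolysis genes, and the other wild-type arrays between -0.087 and 0.14. Without wild-type 1 the hypoxia median was 0.046 (camera adjusted p 0.390) and the glycolysis median 0.024 (0.293), and without FoxO-null 3 they were 0.11 (0.0835) and 0.066 (0.0933). The hypoxia median was 0.25 without FoxO-null 1, 0.30 without wild-type 2 and 0.23 without wild-type 3, and the glycolysis median was 0.26 without wild-type 3. The autophagy list had a median of 0.12 with 17 of 23 positive (camera adjusted p 0.00247). For autophagy adjusted p = 0.367 with an estimated correlation. No member passed over all genes in limma (7 unadjusted) and 0 when adjusted over the list alone, or 1 without FoxO-null 2 or FoxO-null 3; Wipi1 was at 0.67 ± 0.19 and Map1lc3b at 0.39 ± 0.12. The autophagy median was 0.20 without FoxO-null 2, 0.26 without FoxO-null 3 and 0.24 without wild-type 3.

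The other FoxO target classes did not pass. Targets of cell cycle arrest and DNA damage had a median of 0.00018 (camera adjusted p 0.999). The CDK inhibitor gene Cdkn1c, at 1.02 ± 0.26 (830 ± 69.4 against 437 ± 185, adjusted p 0.221), was the 1 member past the threshold when adjusted over the list alone. Its wild-type arrays 1 to 3 read 231, 492 and 588, and its log2 fold change was 0.62 without wild-type 1. Cdkn1a was at -0.32 ± 0.11 (0.355), Cdkn1b at 0.18 ± 0.18 (0.772) and Ccng2 at -0.057 ± 0.17 (0.940). FoxO apoptosis targets had a median of 0.071 (camera adjusted p 0.999), with Bnip3 at 0.43 ± 0.18 and Pmaip1 at -0.69 ± 0.31. Antioxidant and redox genes had a median of 0.042 (camera adjusted p 0.824). Adjusted over the list alone, 2 of them passed, the metallothionein gene Mt3 as higher at 0.57 ± 0.12 and the thioredoxin reductase gene Txnrd1 as lower at -0.41 ± 0.11, while Cat was at 0.34 ± 0.12 (0.369) and Sod2 at 0.029 ± 0.11 (0.954). The FoxO family list had 3 measured members, too few for camera; 1 passed over all genes and 3 passed as higher when adjusted over the list alone, Foxo3 at 0.66 ± 0.25 (adjusted p 0.404 over all genes, and 0.31 on the log2 scale without wild-type 1) among them.

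Growth factor and Wnt lists did not pass camera either. The mixed test of fry passed for Wnt/beta-catenin targets (fry mixed adjusted p 0.00319), PI3K-AKT-mTOR (0.0108), extracellular matrix (0.0159) and antioxidant genes (0.0332). That test disregards sign, so a pass does not show that members moved both ways. The G2/M list, with 40 of 41 members negative, passed it too (fry mixed adjusted p 0.0067). Of the lists past camera, hypoxia (fry mixed adjusted p 0.453), glycolysis (0.323), autophagy (0.325) and dorsal genes (0.365) did not pass it. PI3K-AKT-mTOR and growth factor receptor genes had a median of 0.0090 (camera adjusted p 0.999); adjusted over the list alone 3 passed, Igf1r as higher at 0.62 ± 0.14 and Igfbp4 and Akt1 as lower, Akt1 at -0.39 ± 0.11. Wnt/beta-catenin targets had a median of -0.14 (camera adjusted p 0.272), or -0.056 without wild-type 3 and -0.24 without FoxO-null 2 (0.0898); adjusted over the list alone 3 passed, Id2 as higher and Ccnd1 and Myc as lower, Myc at -0.65 ± 0.16. Axin2, a feedback target of Wnt, was at -0.12 ± 0.16 (adjusted p 0.845) and Lef1 at 0.40 ± 0.59 (0.860). Wnt ligands, receptors and effectors had a median of 0.15 (camera adjusted p 0.739), or 0.051 without wild-type 2, 0.074 without FoxO-null 3 and 0.080 without wild-type 1, with Tcf7l1 at 0.57 ± 0.16 and Fzd1 at -0.57 ± 0.17. Wnt antagonists had a median of -0.0012 (camera adjusted p 0.999), with the secreted antagonist gene Sfrp2 at 0.44 ± 0.13 (0.283), Sfrp1 at 0.023 ± 0.24 (0.986) and Kremen1 at -0.37 ± 0.19. Sonic hedgehog pathway genes had a median of 0.0012 (camera adjusted p 0.999), with Ptch1 at 0.24 ± 0.11 and Gli2 at 0.56 ± 0.33.

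Markers of other cell types did not pass as groups. Mean signals of 7 of 23 measured neuronal, 3 of 5 microglial and 5 of 10 endothelial markers were not above the highest bacterial control. This limits what these lists can show. Neuronal markers had a median of 0.038 (camera adjusted p 0.824). The growth cone gene Gap43, at -0.74 ± 0.18 (777 ± 158 against 1311 ± 306), was the 1 member past the threshold when adjusted over the list alone, Tubb3 was at -0.64 ± 0.27 and Dcx at 0.16 ± 0.22 (adjusted p 0.847). Microglia and leukocyte markers (median 0.063), endothelial, mural and fibroblast markers (0.030) and ependymal and choroid plexus markers (-0.060) each had a camera adjusted p of 0.999. In these, the microglial genes C1qb and Lyz2 were at 0.47 ± 0.54 and 0.46 ± 0.53, Flt1 at 0.58 ± 0.60, Fbln1 at -0.21 ± 0.18, and the choroid plexus genes Clic6 and Folr1 at 0.75 ± 0.34 and -0.73 ± 0.36. All 3 Folr1 signals of the lines labelled FoxO-null lay within the bacterial controls, which bounds its ratio at 1.42-fold or more.

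Among the remaining lists, cholesterol biosynthesis genes had a median of 0.088 (camera adjusted p 0.119), and the lanosterol synthase gene Lss, at 0.45 ± 0.11, was the 1 member past the threshold when adjusted over the list alone, with Insig1 at 0.25 ± 0.11. This list passed without FoxO-null 2 (median 0.14, camera adjusted p 0.0152), and its median was 0.031 without FoxO-null 3. Extracellular matrix and adhesion genes had a median of 0.11 (camera adjusted p 0.999), which was 0.0017 without FoxO-null 3, 0.012 without wild-type 1 and 0.019 without FoxO-null 2; 2 passed as higher when adjusted over the list alone, the proteoglycan gene Ncan at 0.60 ± 0.14 and the membrane protease gene Mmp14 at 0.60 ± 0.15. Ventral telencephalic patterning genes had a median of 0.24 (camera adjusted p 0.415; 0.057 without wild-type 3), with Meis2 at 0.44 ± 0.17 and Gsx2 at 0.79 ± 0.47, and posterior neural and Hox genes one of -0.28 (0.667), with Pax5 at 1.39 ± 0.52 and En2 at -1.32 ± 0.75. The posterior list passed as lower without wild-type 1 (median -0.56, camera adjusted p 0.0224) and had a median of -0.17 without wild-type 2 or wild-type 3. Immediate early and heat shock genes had a median of -0.015 (camera adjusted p 0.625), with Hsp90aa1 at -0.37 ± 0.13 and Egr1 at -0.55 ± 0.19. They passed as lower without wild-type 1, the array with the high 18S rRNA control (median -0.25, camera adjusted p 0.0462). Interferon and MHC class I genes had a median of 0.083 (camera adjusted p 0.999), which was -0.084, -0.028 and -0.0036 without wild-type 1, 2 and 3, with H2-K1 at 0.46 ± 0.19 and Ifi27 at -0.85 ± 0.37. Sex-linked markers had a median of 0.81 (camera adjusted p 0.625), with Kdm5d at 1.14 ± 0.76 and Eif2s3y at 1.53 ± 1.20. In 7 lists, none of which passed, the median and the camera direction differed in sign: the neuronal, FoxO arrest, FoxO apoptosis, extracellular matrix, endothelial, interferon and Sonic hedgehog lists.

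Leaving out 1 array moved the following values, none of them past the threshold with all arrays, by over 1.5 times or across 0. List medians of cell types ranged as follows: neuronal from -0.023 to 0.088, microglial from -0.033 to 0.21, endothelial from -0.12 to 0.21 and ependymal from -0.23 to 0.090. Those of FoxO targets and pathways ranged for FoxO arrest targets from -0.042 to 0.13, FoxO apoptosis targets from 0.017 to 0.15, antioxidant genes from 0.010 to 0.088, PI3K-AKT-mTOR genes from -0.026 to 0.039 and Sonic hedgehog genes from -0.082 to 0.061. Further medians ranged for Wnt antagonists from -0.10 to 0.0010, immediate early genes from -0.25 to 0.058 and sex-linked markers from 0.33 to 1.62. Among genes of the lists that passed, the log2 fold change ranged for Aldoc from 0.36 to 0.78, Higd1a from 0.23 to 0.47, Emx2 from 0.25 to 0.77, Olig2 from -0.25 to -0.089 and Sox2 from -0.0083 to 0.19. In FoxO target, redox and hedgehog lists it ranged for Bnip3 from 0.20 to 0.62, Cdkn1b from 0.020 to 0.38, Ccng2 from -0.24 to 0.13, Sod2 from -0.044 to 0.083 and Gli2 from 0.19 to 0.76. In Wnt lists the ranges were Axin2 from -0.24 to -0.016, Lef1 from 0.051 to 1.005 and Sfrp1 from -0.20 to 0.15. In cell type lists they were Dcx from -0.024 to 0.30, C1qb from -0.10 to 0.86, Lyz2 from 0.20 to 0.93, Flt1 from 0.11 to 1.15, Fbln1 from -0.31 to -0.063, Clic6 from 0.34 to 1.02 and Folr1 from -0.89 to -0.47. In the other lists they were Meis2 from 0.25 to 0.59, Gsx2 from 0.48 to 1.12, En2 from -2.32 to -0.67, Egr1 from -0.71 to -0.33, H2-K1 from 0.22 to 0.60, Ifi27 from -1.20 to -0.41, Kdm5d from 0.29 to 2.02 and Eif2s3y from 0.77 to 2.97.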

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

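The tests of exchanged labels, of background noise, of probe sets outside the deleted exons and of a lower share of progenitor cells, including its limits on marker signal and its scores per array, were chosen only after the results they measure had been seen, and the block on the Xist state was added after the sex-linked signals had been seen. No single result stood apart by the rules set for this part: groups of 3 arrays are not tested for outlying arrays, the design holds a single contrast, and of 3945 probe sets without a named gene 0 passed the limma threshold (217 at an unadjusted p under 0.05). Directions follow the labels, which the FoxO signals go against.

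The first pattern weighed is that FoxO transcripts were higher in the lines labelled FoxO-null. Background noise at low signal is argued against for single probe sets only. Each of the 3 genes taken as targeted had a probe set that met a rule set after the values were seen. Its arrays labelled FoxO-null all lay above the bacterial controls of their array and above every wild-type array. The highest bacterial controls were themselves higher on the arrays labelled FoxO-null, 19.2 to 27.6 against 14.4 to 19.1. The other Foxo4 probe set did not share the rise, with means of 24.7 ± 11.8 and 31.0 ± 8.33. Its groups overlapped at signals of 15.3 to 40.2, near the bacterial controls, so it shows no clear direction. Exchanged group labels stay open, since the 44 pooled FoxO targets had a median log2 fold change of 0.086 with 26 positive and 18 negative (camera p 0.129, and 0.358 with an estimated correlation), while its metabolism class was higher on all 3 arrays labelled FoxO-null (median 0.32, camera adjusted p 0.0145, but adjusted p = 0.253 with an estimated correlation) and its other classes did not pass (camera adjusted p 0.999 each). Probe sets outside the deleted exons stay open as a reason why signals were not lower, since 0 could be placed. The mean over the 9 probe sets was higher by 1.18 (95% t interval 0.91 to 1.46). That interval restates the pattern and cannot show where the probe sets lie. An increase of untranslatable FoxO transcripts after deletion is a biological possibility that was not tested, and it cannot be told apart from exchanged labels with these values.

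The second pattern weighed is that cell cycle genes were lower and glial genes higher in the lines labelled FoxO-null, a difference of medians of 0.76 between 39 glial and 79 cell cycle genes. A difference in sex between the groups is argued against, since the difference was 0.79 with the Xist state as a block, with glial medians of 0.46 and 0.38 and cell cycle medians of -0.27 and -0.37 within Xist-high and Xist-low lines, where each comparison has 1 line on one side. The difference was 0.76 after quantile normalization, but a scale factor of an array moves both sets of genes alike and cancels in it. This value therefore cannot test array scaling. Each of the glial and cell cycle lists kept its direction in 21 alternatives, which included quantile normalization and median centring. Medians ranged from 0.32 to 0.51 for astrocyte and 0.40 to 0.59 for oligodendrocyte genes. They ranged from -0.45 to -0.29 for G1/S and -0.41 to -0.29 for G2/M genes. A lower share of progenitor cells stays open. Among markers above background, the median of 38 glial genes exceeded that of 23 neuronal, microglial and endothelial genes by 0.43. The 95% bootstrap interval over genes was 0.28 to 0.69, from 10000 draws. For the 14 of these other genes with a signal under 100, where a high baseline hides less, the excess was 0.51 (0.29 to 0.77). Scored per array, the difference between the groups was 0.57 (95% t interval 0.13 to 1.01). These values show only that other markers were not raised as much as glial ones. They cannot decide, since the glial lists were weighed because they were higher on the same arrays. Fewer progenitors also need not raise markers of every other type alike. The neural stem and progenitor list itself had a median of 0.10 with 17 of 29 members positive. A larger share of cells entering glial lineages, and an effect of the FoxO deletion within cells, may both apply and were not separated, and the direction of either stays open with the labels.

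The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of the 10, only 1, the real one, gave as many as 5 changed genes (highest other 2), 1 as many as 3 genes changed at least 2-fold (highest other 2) and 1 as many as 14 shifted lists (highest other 10). At an unadjusted limma p under 0.05 the real one gave 1292 genes and the others 320 to 1017.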

How the results depend on the processing

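The Xist block was chosen after seeing the data; the other alternatives were set before. Directions follow the labels. Against 5 genes changed, 4 higher, 1 lower and 3 at least 2-fold, the counts were 1, 1, 0 and 1 with quantile normalization, with the offset at the 5th percentile, with no filter on low values, with the mean over all probe sets, without _s_at, _x_at and _a_at probe sets and with every probe set tested. They were 0, 0, 0 and 0 with median centring and with eBayes without a trend in limma (1048 and 1116 genes at an unadjusted p under 0.05). Array weights gave 24, 21, 3 and 9, an adjusted p under 0.10 gave 17, 14, 3 and 5, and the Xist block gave 2 changed, 2 higher and 0 lower. The lower count was 2 with the offset at the 50th percentile and with robust eBayes. Leaving out 1 array gave 0 to 13 changed, 0 to 12 higher, 0 to 2 lower and 0 to 10 at least 2-fold. The replicate number as a block (replicate block) gave 6 changed genes and 14 lists; same-numbered lines deviated together at r of 0.023, 0.091 and 0.12, 5 of 6 lines correlated best with their own number but wild-type 1 did so with FoxO-null 2 (0.078), and the numbers were not taken as pairs.

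Lists past the threshold were 0 with an estimated correlation and 3 with fry against 14, and 10 to 13 with 1 array left out. The neural stem and progenitor list turned to -0.0083 without FoxO-null replicate 2 and reached 0.18 without FoxO-null replicate 3. The log2 fold change of Foxo4 kept its direction but not its call with quantile normalization (3.23), median centring (3.18), the offset at the 5th percentile (3.81), no filter on low values, no _s_at, _x_at and _a_at probe sets, every probe set tested and eBayes without a trend (3.24 each) and the mean over probe sets (1.46), which takes in the probe set that disagrees. It ranged from 2.96 to 3.77 with 1 array left out. The log2 fold change of Foxo1 passed with array weights (1.59) and without wild-type replicate 3 (1.78) and ranged from 1.499 to 1.78 with 1 array left out. Foxo3 ranged from 0.31 to 0.90 with 1 array left out and passed in no setting. Beyond the smaller number of arrays or the larger number of tests in some settings, the cause was not tested. Of 21 alternatives, camera calls held in 19 or 20 for the autophagy, glial, cell cycle, microcephaly and p53 lists, in 17 for the BMP and FoxO metabolism lists, 16 for hypoxia and glycolysis, 14 for stem cell markers and 13 for the Notch and dorsal lists. Of the other results, 43 single gene values and 51 list medians lost a call with the same direction, 18 and 3 gained one, 26 and 59 changed sign without a call in either setting, and 1544 and 570 kept both; the median of all genes stayed between -0.058 and 0.026. Signals near the bacterial controls, between 14.4 and 27.6, limit what weakly expressed genes can show. These controls reached 19.2 to 27.6 on the arrays labelled FoxO-null and 14.4 to 19.1 on those labelled wild-type.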

Other observations

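Both tests of this part were written down before the other list members had been examined as a set, but the patterns that prompted them were found in the same data. Directions follow the labels, which the FoxO signals go against.

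Ribosome biogenesis genes were lower in the lines labelled FoxO-null. The list was drawn up after Nolc1 and Srm had been seen to be lower, and Nolc1 was left out of its test. Of the 33 other measured members, 32 were negative, with a median log2 fold change of -0.22 (bootstrap 95% interval over genes -0.30 to -0.20). That interval does not measure the spread between lines. Genes that vary with Nolc1 would follow it on these arrays, so leaving it out gives no independent test. The list was not refitted with 1 array left out. Limma's camera gave p 1.26e-09 with the preset correlation and p = 0.0239 with an estimated correlation, and fry gave p 0.0108, none of them adjusted over other lists. The snoRNP protein gene Rrp9 was at -1.09 ± 0.27 (55.6 ± 17.1 against 127 ± 44.0), Gar1 of the box H/ACA complex at -0.59 ± 0.16, the pseudouridine synthase gene Dkc1 at -0.50 ± 0.16 and Nhp2 at -0.34 ± 0.10. None of these passed over all genes, the limma adjusted p of Nolc1 being 0.136 and that of Rrp9 0.202. A lower output of ribosome biogenesis may accompany the lower cell division transcripts; whether it follows from them was not tested.

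A second hypothesis, lower output of MAPK-ERK signalling, came from the phosphatase genes Dusp6 at -0.80 ± 0.17 and Dusp4 at -0.61 ± 0.13 and from Ccnd1, none of which passed over all genes. The 16 other measured feedback and target genes had a median log2 fold change of -0.077 with 10 negative (bootstrap 95% interval -0.17 to 0.055; camera p 0.211, and 0.343 with an estimated correlation). Egr1, at -0.55 ± 0.19, and Ier3 also belong to a list fixed earlier, and without them the 14 remaining genes had a median of -0.077 with 8 negative (camera p 0.431, and 0.569 with an estimated correlation). The criterion set in advance would have taken a missed threshold as exclusion, which it is not. The interval, taken over genes, holds both 0 and values down to -0.17, and it does not measure the spread between lines. The verdict was changed to open after the result was seen.

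Control values of single arrays were as follows. The Y-linked gene Eif2s3y read 132, 117 and 93.8 on FoxO-null 1, FoxO-null 3 and wild-type 3, and 0.57, 0.36 and 1.34 on FoxO-null 2, wild-type 1 and wild-type 2, the arrays with high Xist. The ratio of the 3' to the 5' control probe set lay between 0.79 and 0.93 for Gapdh and between 1.03 and 1.12 for Actb on the 6 arrays.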
